A study of Mus musculus with 25 samples.

How the data were processed

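The samples were 25 single cells from the arcuate nucleus and median eminence of 2 pooled adult male RIP-Cre mice of a (C57BL/6 x DBA)F2 background. Per the labels' protocols, the tissue was digested with papain and dispersed, GFP-positive cells were picked by hand and frozen singly, and polyadenylated RNA was made into libraries with Smart-Seq2 and Nextera XT. Smart-Seq2 amplifies cDNA over the length of transcripts, carries no molecular identifiers and marks no strand, so reads are not independent molecules and overlapping genes on opposite strands cannot be told apart.

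The authors deposited 1 table of genes by cells, whose values are RPKM by their form, although it is named as gene counts. The values are decimals, low values multiplied by the exon length of the gene fell on steps of 1, 2 and 3 reads, and value times exon length summed to nearly the same total in every cell (coefficient of variation 1.72%). Per the submitters' processing notes, the tools were bcl2fastq, TopHat2 2.0.14, Picard 2.5.0, SAMtools 0.1.19 and featureCounts 1.4.6 and the builds mm10 and GRCm38; the notes used here give no role or order for them, and the gene annotation, the use of Picard and whether reads were paired are not given in the sources used here. The plan written before the data were examined assumed counts scaled to CPM. Since the values are RPKM, every level of 10 CPM was read as 10 RPKM, the pseudocount of 1 CPM as 1 RPKM, and library sizes rescaled from counts, also foreseen in the plan, were not computed. RPKM divides by gene length, so 10 RPKM asks for more reads of a long gene than of a short one.

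The table held 33082 rows. The 26 rows whose names had become spreadsheet date numbers were left out, and for 757 symbols on more than 1 row the row with the highest sum was kept, which left 30903 symbols. All 25 value columns were used. Exon lengths and positions came from GENCODE M21 (GRCm38), which gave a length for 22754 symbols (73.6%), carrying 95.3% of all RPKM. These lengths may differ from those the authors used. Value times exon length summed, per cell, to 1.366 to 1.452 times the total that matching lengths and read totals would give (median 1.397 times). This excess points to a mismatch in lengths or read totals. Read numbers are therefore estimates, and the size of their error is not known.

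Depth was estimated for each cell from the comb of 1, 2 and 3 reads among its low values. It came to 882700 to 2990000 reads per cell. At these depths, 10 RPKM corresponds to 17.9 reads for a gene of 1 kb in the median cell and 8.83 reads in the shallowest. The step finder was tested on simulated data for 22754 genes at 12 known depths and was off by at most 0.553%. The same lengths served to simulate and to estimate, so an error in the lengths was not covered.

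A gene was called detected in a cell at 10 RPKM or more. Shares of cells were given exact Clopper-Pearson 95% intervals, and a count of 0 was given the limit of 3 in 25 cells. Both cover counting error only. Co-detection of 2 genes was set beside the product of their shares and the central 95% range of the hypergeometric distribution, as a description of these cells. Gene lists were fixed before the data were examined: markers of neurons and of 9 other cell classes, of hypothalamic neuron types, and lists of transmitter, neuropeptide, insulin-related, receptor, transcription factor, channel, immediate early, heat shock, axon growth, sex-linked, oxidative phosphorylation, ribosomal protein, synaptic release and circadian genes. The genes named were chosen by a rule fixed at the same time: from each list up to 8 members (15 for neuropeptides) detected in most cells, with ties broken by mean level, and up to 4 in no cell; each peptide that leads the list in a cell; Ins1, Ins2, Lepr, Pomc, Agrp, Npy, Th, Slc32a1, Slc17a6 and Rgs9; the 20 most variable genes; and the top 10 genes of each cluster. The marker lists were read in the same way. Genes and pairs outside the rule, such as Bsx, Kcnj11, Abcc8, Sstr2 with Sst and single-cell findings, were singled out after their values were seen. The plan named no pair of genes, so no reported pair, such as Lhx1 with Th or Gal with Cartpt, was fixed in advance. Some genes that the rule would name are not reported here.

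Clustering used 9783 genes at 10 RPKM or more in at least 3 cells. The 1000 genes with the largest residual of log squared coefficient of variation on log mean were taken as log2(RPKM + 1), centred and reduced to 5 principal components, joined by Ward linkage, and divided into the number of clusters from 2 to 6 with the highest mean silhouette. The silhouette was set beside 100 data sets in which each gene was shuffled over the cells. A cluster was named only where at least 3 markers of a type were detected in most of its cells and its leading genes did not contradict the name; clusters below 3 cells stayed unnamed. After the values were seen, a name was further withheld where no marker of the type was among the 10 leading genes. Coherence of a list was the mean pairwise Pearson correlation over cells, for lists with at least 4 genes at 10 RPKM in 3 cells, ranked among 10000 random lists drawn from 20 expression bins. Both steps were tested on simulated data made from shuffled real values of 9783 genes. With 3 clusters planted in 400, 200 or 100 of the variable genes, the step chose 3 clusters in 20, 16 and 8 of 20 data sets; at 3 clusters the lowest adjusted Rand index was 1, 0.868 and 0.754. A planted list ranked in the top 2.5% in 20 of 20 data sets at each size, and 1 of 60 random lists did. Planted genes had their own highest values moved into the cells of 1 planted cluster, the sharpest separation their values allow. Recovery of weaker patterns was not tested.

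To see how the results depend on these choices, the detection level was changed to any value above 0, to 100 RPKM or to 10 estimated reads, each cell was thinned to the depth of the shallowest, weak cells were left out, and the pseudocount, the kind of correlation, the number of variable genes, the linkage, the components and the gene filter were changed. Settings added after seeing the data were a level of 1 RPKM, rescaling of each cell to the same sum of RPKM, and leaving out the 6 cells with Malat1 under 20 RPKM. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scikit-learn 1.9.0.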

Results

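Messenger RNA was measured in 25 single cells from the arcuate nucleus and median eminence at the base of the mouse hypothalamus. The donors were RIP-Cre mice, in which Cre recombinase is driven by a rat insulin promoter, and the picked cells carried green fluorescent protein (GFP) from a virus that is expressed only after Cre recombination. All 25 cells came from a pool of 2 adult male mice with an average age of 63 days. They form 1 group and 1 pooled sample, so no test between groups was possible, cells were not treated as replicates, and no p-value is given. The question addressed was which kinds of cell the GFP label had marked. Cells are named by the numbers in their labels, and a gene was counted in a cell at 10 RPKM (reads per kilobase of gene, scaled to the depth of the cell) or more. Depth, estimated from the steps between low values, ranged from 882700 reads in cell 9 to 2990000 reads in cell 11, with a median of 1790000 reads. A median of 4896 genes reached 10 RPKM per cell, with a range of 3843 (cell 43) to 6183 (cell 29). The 50 highest genes of at least 0.5 kb averaged 305 to 687 RPKM per cell, equal to 0.543 to 0.937 reads per base at these depths. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error over the picked cells only, and a gene seen in 0 of 25 cells could still mark up to 12% of such cells.

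All 25 cells had the profile of neurons. The synaptic protein gene Snap25, the neuronal tubulin Tubb3, the growth-associated tubulin regulator Stmn2 and the ubiquitin hydrolase Uchl1 were detected in 25 of 25 cells (100%, interval 86.3 to 100%), at median levels of 337, 259, 100.1 and 397 RPKM. Each cell held at least 7 of the 12 neuronal markers, with a median of 10. Syt1, Elavl4 and Nefl reached the level in 22 cells each, Map2 in 21, Elavl3 in 19 and Rbfox3, which encodes NeuN, in 18. In contrast, no cell held more than 25% of the markers of any non-neuronal class. Every microglial complement gene (C1qa, C1qb, C1qc), the endothelial gene Cldn5, the oligodendrocyte genes Mog and Mobp and the precursor gene Pdgfra stood at 0 in all cells, as did the pituitary hormone genes Tshb, Cga and Prl, while Gh reached 15.2 RPKM in cell 4 and was listed at 0 elsewhere. The astrocytic water channel gene Aqp4 and the mural gene Acta2 were below 10 RPKM throughout, and Rax of tanycytes was listed at 0. A few genes of the non-neuronal lists were nevertheless frequent: Aldoc in 20 cells (median 91.7 RPKM), Mbp in 14 (23.3 RPKM) and Lhfpl3 in 14 (26.7 RPKM).

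Most of the cells carried the genes for GABA synthesis. Gad1 and Gad2, the glutamate decarboxylases, were detected in 23 of 25 cells (92%, interval 74.0 to 99.0%) and 19 of 25 cells (76%, interval 54.9 to 90.6%), and 24 cells had at least 1 of them. The vesicular GABA transporter Slc32a1 was at the level in 10 cells (40%, interval 21.1 to 61.3%), and was listed above 0 in 21. All 10 had Gad1, against 9.2 expected for independent genes and a range of 8 to 10 for the central 95% of random overlaps. That range ends at the largest overlap possible, so this overlap could not have exceeded it. The vesicular glutamate transporter Slc17a6 was detected in 2 cells, 7 and 27, at 149 and 20.7 RPKM, and these were the same 2 cells in which Gad1 was listed at 0. Cell 27 still held Gad2 at 109 RPKM, whereas cell 7 had 0.86 RPKM. Both cells expressed Sox14, and each carried other genes known from the neighbouring ventromedial hypothalamus: cell 7 had the peptide gene Adcyap1 at 220.5 RPKM and the transcription factor Fezf1 at 85.4 RPKM, and cell 27 had Nr5a1 at 96.6 RPKM. These other genes were not shared: Nr5a1 was listed at 0 in cell 7, and Adcyap1 and Fezf1 at 0 in cell 27. Slc17a8 reached the level in cells 27 and 31, and Slc17a7 in none.

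Genes of dopamine synthesis were detected together in a subset of the cells. Th, tyrosine hydroxylase, the rate-limiting enzyme of catecholamine synthesis, was detected in 8 of 25 cells (32%, interval 15.0 to 53.5%) with a median of 306 RPKM and a highest value of 784 RPKM in cell 12. All 8 Th cells also had Gad1 and all 8 had Ddc, the decarboxylase that follows Th. The random range was 6 to 8 for Gad1 (7.36 expected) and 4 to 8 for Ddc (5.76 expected), which was detected in 18 cells. Both ranges end at 8, the largest overlap possible, so neither overlap could have exceeded its range. The vesicular monoamine transporter Slc18a2 was detected in 9 cells, 6 of them with Th, where 2.88 would be shared by independent genes and the central 95% of random overlaps spans 1 to 5. The cofactor enzyme Gch1 was found in 9 cells and shared 5 with Th, within the random range of 1 to 5. The dopamine reuptake transporter Slc6a3 was detected in 2 cells, 11 and 12, both with Th. Here too the random range of 0 to 2 ends at the largest overlap possible. Other monoamine and acetylcholine genes were seen in 1 cell each: the histamine enzyme Hdc in cell 15 (169 RPKM), Dbh in cell 6, Tph2 in cell 34 and Slc18a3 in cell 9. Chat, Slc5a7 and Slc6a4 were in none.

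Neuropeptide genes were examined because they conventionally separate types of arcuate neuron. Of 39 listed genes, 26 were detected in at least 1 cell, with a median of 7 per cell and a range of 3 (cell 4) to 11 (cell 29). The secretory granule genes Scg2 and Chgb were in all 25 cells and Vgf in 14, and each cell had at least 1 further gene of the list. In cell 5 this was Cbln2 alone (77.7 RPKM), and in cell 27 Hcrt alone, at 10.3 RPKM, just above the level. Cartpt, Penk, Pomc and Pnoc were found in 10 cells each (40%, interval 21.1 to 61.3%), Agrp in 9, and Sst, Gal, Pthlh and Cbln2 in 5. The level of these genes differed widely. Sst, which encodes somatostatin, was the most abundant peptide gene in its 5 cells (1, 6, 9, 25 and 31), with values of 710 to 1577 RPKM, and was listed at 0 in the other 20. Pomc, the precursor of melanocortins, reached 481 RPKM in cell 29 and 232 RPKM in cell 43, while the other 8 Pomc cells lay between 11.0 and 70.2 RPKM. The peptide genes Ghrh, Nts, Avp, Nmu, Adcyap1, Rln3 and Gnrh1 were each seen in 1 cell, among them Avp, vasopressin, at 219 RPKM in cell 43 and Ghrh at 60.5 RPKM in cell 11.

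Among the feeding-related peptides, Agrp was detected in 9 cells (36%, interval 18.0 to 57.5%) but never above 50.6 RPKM. Its usual partner Npy reached the level in 2 of them, at 90.9 RPKM in cell 29 and 208 RPKM in cell 34, and was listed at 0 in the other 7. Pomc and Cartpt were found together in 7 cells, against 4 expected for independent genes and a random range of 2 to 6. Overlaps were counted at 10 RPKM only and were not rerun at other levels. Pomc was listed above 0 in 18 cells and Cartpt in 15. Gal, encoding galanin, was detected in 5 cells that all also had Cartpt, against 2 expected and a range of 0 to 4. This pair was not named in the plan. Sst and Th shared 1 cell (cell 1), within the range of 0 to 3. No cell reached the level for Tac2, Crh, Oxt, Vip, Cck or Pmch, and Kiss1, Tac1 and Npff were not analysed here.

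**Figure D1:**
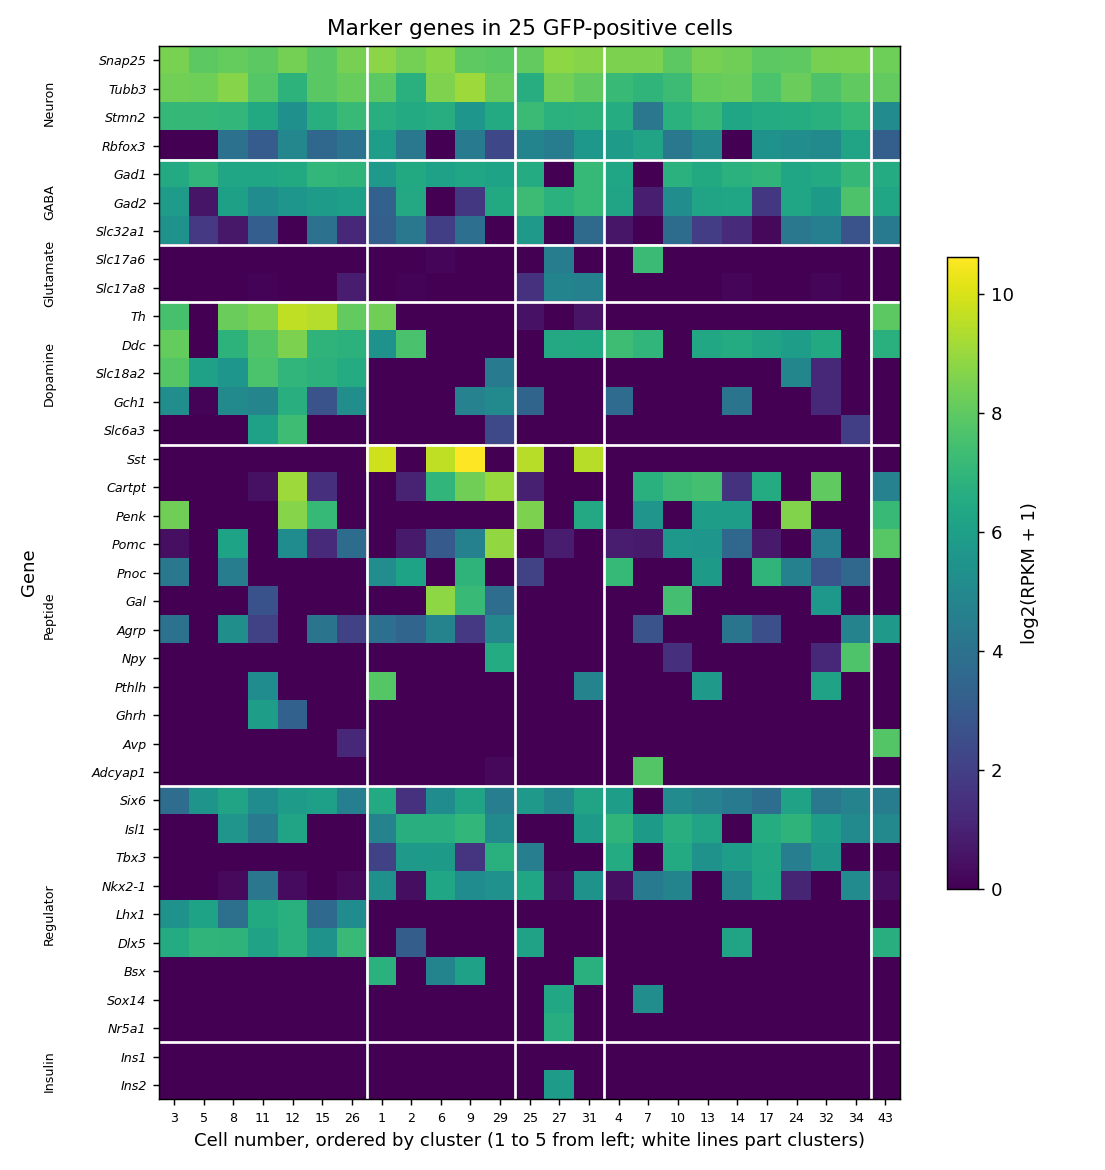
Heat map of log2(RPKM + 1) for marker genes (rows, grouped by list) in each of the 25 GFP-positive cells (columns, ordered by cluster and then cell number). Snap25, Tubb3 and Stmn2 fill every column, Gad1 is missing from cells 7 and 27, Th and Lhx1 share the first block of 7 cells except for cell 5, which lacks Th, and Sst is high in 5 cells.

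The receptor genes for circulating hormones were led by nuclear receptors. A median of 7 of 25 listed genes was detected per cell, from 3 in cell 12 to 12 in cell 11. The glucocorticoid receptor Nr3c1 and the thyroid hormone receptor Thra were each found in 23 cells (92%, interval 74.0 to 99.0%), and Fgfr1 and Adipor1 in 15 (60%, interval 38.7 to 78.9%). The oestrogen receptor Esr1 was detected in 11 cells. Among receptors of peptide hormones, Glp1r, the receptor of glucagon-like peptide 1, was found in 10 cells at a median of 59.8 RPKM and was listed at 0 in the other 15. The prolactin receptor Prlr was in 10 cells, the insulin receptor Insr in 9, the ciliary neurotrophic factor receptor Cntfr in 9 and the calcitonin receptor Calcr in 7. They were listed above 0 in 17, 18, 16 and 8 cells. For the long genes Prlr and Insr, 10 RPKM at the median depth is 275 and 246 reads. The leptin receptor Lepr reached the level in 0 cells. It was listed above 0 in 12, with a highest value of 2.73 RPKM in cell 29. Mc4r, Gipr and Il6ra were also in 0 cells. All 10 Glp1r cells had Fgfr1, a pairing picked after the values were seen, where 6 would be expected and the random range is 4 to 8.

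**Figure D2:**
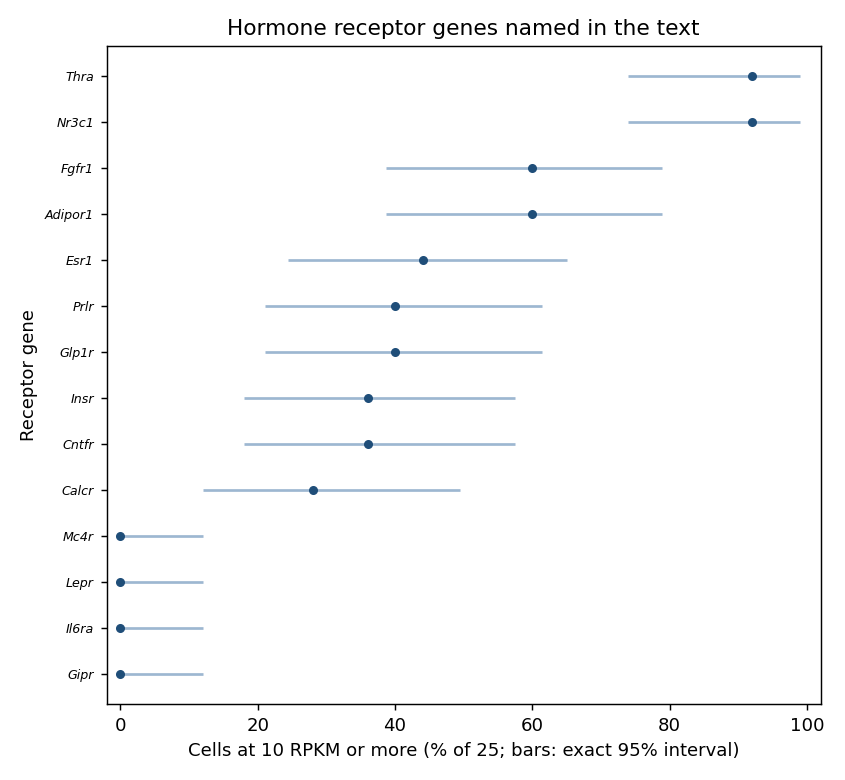
Percent of the 25 cells with each of the hormone receptor genes named in the text at 10 RPKM or more (points), with exact 95% intervals for counting error (bars); for genes in 0 cells the bar runs to the limit of 12%. Thra and Nr3c1 stand at 92%, Glp1r and Prlr at 40%, and Lepr at 0.

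Of 33 listed receptor genes for neuropeptides and transmitters, a median of 5 was detected per cell. The nociceptin receptor Oprl1 was the most frequent, in 21 cells (84%, interval 63.9 to 95.5%), followed by the somatostatin receptor Sstr1 in 12, the neuropeptide Y receptor Npy2r in 11, Sstr2 in 8 and Crhr2 in 7. Sstr2 was detected in 4 of the 5 Sst cells, above the random range of 0 to 3. Htr1a was detected in no cell. Of the 21 channel and ionotropic receptor genes, the AMPA receptor subunits Gria2 and Gria1 were found in 24 and 22 cells, and the NMDA receptor subunits Grin1 and Grin2b in 21 and 18. The subunits of the ATP-sensitive potassium channel were sparse, with Abcc8 in 3 cells and Kcnj11 in 2, and no cell held both. With so few cells for each gene, independent genes would often share none, so the missing overlap says little.

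A median of 8 of 39 listed transcription factor genes was detected per cell, from 4 in cell 7 to 12 in cell 25, and 8 of the 39 were in no cell. Six6 and Six3 were detected in 23 and 22 cells (92% and 88%), Isl1 in 18 (72%), Dlx2 in 13, Nkx2-1 in 12, Tbx3 in 11 and Dlx5 in 10. Lhx1 was found in 7 cells, all with Slc18a2 and Dlx5 and 6 of them with Th. For Lhx1 and Th, 2.24 shared cells were expected for independent genes, with a range of 0 to 4. These pairs were not named in the plan. Lhx1, Th, Slc18a2 and Dlx5 are also among the leading genes of 1 cluster of these same cells, described below. Bsx, singled out after its values were seen, was detected in 4 cells, all of them Sst cells (0.8 expected, range 0 to 2). Otp was in 4 cells, Gsx1 in 2 and Nkx2-4 in 1, and Lhx6, Meis2, Ebf3 and Zic1 were among those in none. Over the 56 transmitter, peptide, receptor and transcription factor genes detected in 4 to 21 cells, 49 of 1540 gene pairs overlapped more than the random range and 19 less, where 12.8 and 7.89 are expected for independent genes.

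The mouse insulin genes were examined because an insulin promoter drives Cre in these mice, and they were almost undetected. Ins1 was listed at 0 in all 25 cells, and Ins2 was detected in 1 cell, cell 27, at 58.3 RPKM. Ins2 lies on chromosome 7 from 142678656 to 142743381 and Th on the same chromosome from 142892752 to 142931128 (GRCm38), and cell 27 had Th at 0. Of the pancreatic beta cell regulators, Pdx1, Mafa, Neurod1 and Nkx6-1 were listed at 0 in all cells, while Insm1 was detected in 5 cells and Isl1 in 18. The glucose transporter gene Slc2a2 reached the level in none. Rgs9, a regulator of G-protein signalling, was detected in 16 cells (64%, interval 42.5 to 82.0%) at a median of 21.4 RPKM. Transgene sequences were not analysed here.

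Unsupervised clustering on the 1000 most variable genes gave 5 clusters of 7, 5, 3, 9 and 1 cells. The cluster of 7 (cells 3, 5, 8, 11, 12, 15 and 26) is called dopamine-like, since Th, Ddc, Slc18a2 and Gch1 were each detected in most of its cells. Of the other dopamine markers, Slc6a3 was detected in 2 of its cells and Nr4a2 in none. Ddc was also detected in most cells outside the cluster. The leading genes of the dopamine-like cluster were Lhx1os, Th, Gpr83, Slc18a2, Coch, Lhx1, Dlx5, Gm9866, Fstl4 and Tgfb2. The clusters of 9 and 5 each held 3 Pomc markers in most of their cells, with Isl1 in 8 and 5, Tbx3 in 7 and 3 and Cartpt in 5 and 3. Pomc itself was in 4 of the 9 and 2 of the 5 cells, and no Pomc marker was among the 10 leading genes of either, so both were left unnamed, a choice made after these values were seen. The cluster of 5 (cells 1, 2, 6, 9 and 29) was led by Sst, Pth2r and Rem2, the cluster of 3 (cells 25, 27 and 31) by Ifi27, Adamts1 and Sst, and the cluster of 9 by Yjefn3, H2-Q2 and Serpine2, while cell 43 stood alone. The mean silhouette, a measure of separation, was 0.256, and 6 of 100 data sets with each gene shuffled over cells reached as much, up to 0.305. The number of clusters is therefore not separated from shuffled data. Malat1, a nuclear noncoding RNA, was at 16.6 RPKM or less in cells 1, 3, 5, 6, 29 and 31 and at 45.9 RPKM or more in the other 19, and these 6 cells fell into the clusters of 7, 5 and 3. The dopamine-like cluster came back with the same 7 cells in 6 of 9 settings that changed the input. It took in cell 43 under average linkage, lost cells 11 and 12 and gained cell 29 when each cell was rescaled to the same sum, and kept 3 of its 5 remaining cells when 6 cells low in Malat1 were left out. In 100 draws of 500 variable genes, its cells shared a cluster with its other members in 58.7 to 73.7% of draws on average. At 6 clusters, with a silhouette of 0.252, it split into cells 11, 12 and 26 and cells 3, 5, 8 and 15.

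The genes that varied most between cells for their mean level were of several kinds. Of the 20 genes with the highest variation for their mean, Sst, Gal, Cartpt, Pomc and Penk encode peptides, Gpr83, Sstr2, Fzd9 and Qrfpr encode receptors, and Th is a transmitter gene. The others included Crabp1, at 615 RPKM in cell 17 and detected in 3 cells, Serpina3n, at 341 RPKM in cell 29 and detected in 4, and Scgn, which encodes the calcium-binding protein secretagogin, in 5. Among 19 fixed lists with at least 4 usable genes, 7 had a mean pairwise correlation over cells in the top 2.5% of 10000 random lists matched on expression. These were the dopamine markers (mean r = 0.441, the same 4 genes as the usable monoamine list, which is 1 of the 7), the Pomc markers (0.390), ribosomal proteins (0.425), oxidative phosphorylation (0.360), immediate early genes (0.236) and ion channels (0.0779). The Pomc markers used here were Pomc, Cartpt, Tbx3 and Isl1. Neuropeptide, transcription factor, insulin-related and both receptor lists were within the random range, as were the Agrp and Sst marker lists. These percentiles describe the 25 cells and are not tests.

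Immediate early genes, which can respond to tissue dissociation, were unevenly detected. Fos was detected in 24 cells at a median of 427 RPKM, Egr1 in 25 at 186 RPKM, and Jun, Junb and Jund in 23 each. Egr2 was in 6 cells, Ier2 in 4 and Klf2 in 1, and a median of 10 of the 16 genes was found per cell. The heat shock genes Hspa8, Hsp90aa1, Hsph1 and Dnaja1 were in all 25 cells. Hspa1a, which is induced by stress, was in 15 cells at a median of 27.0 RPKM, and Hspa1b stayed below 10 RPKM. As a check of the labels, the X-inactivation gene Xist was below 10 RPKM in all cells, while Tsix, its antisense partner, reached 17.1 RPKM in cell 14. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were detected in 15, 10, 4 and 2 cells. Cells 3, 9, 15 and 43 reached the level for no gene of this list. Their highest Y-linked values were Eif2s3y at 0.53 RPKM in cell 3, Ddx3y at 3.34 in cell 9 and 2.73 in cell 43, and Kdm5d at 2.52 in cell 15. Xist was listed at 0 in these cells.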

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

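The level of 1 RPKM, the rescaling to the same sum and the omission of 6 cells low in Malat1 were chosen after the data were seen, and the other settings before. A level of 100 RPKM, run for shares of cells and for peptide and receptor genes per cell, by its construction keeps abundant genes only. There, cells with at least 6 neuronal markers fell to 12%, cells with Gad1 or Gad2 to 40%, the median number of peptide genes per cell from 7 to 3 and that of hormone receptor genes from 7 to 0. Counting any value above 0 raised the median genes per cell to 7597 and put Gad1 or Gad2 in 100% of cells, as did a level of 10 estimated reads, because cell 7 holds a low Gad2 value. Of 293 named genes, 158 fell below the interval of their share at 100 RPKM, and 43 rose above it when any value above 0 was counted, 16 at 10 estimated reads and 15 at 1 RPKM. After thinning to the shallowest cell 1 gene left its interval and the median was 4672 genes per cell, without the 6 cells 5 left it, and after rescaling 0. The number of lists in the top 2.5% was 7 or 8 in all settings. The circadian list passed that bound with a pseudocount of 10 RPKM, with Spearman correlation (98.7) and without the 6 cells (98.8), and the synaptic release list after rescaling (98.4). The number of clusters moved from 5 to 6 with 500 genes, without the gene filter, after rescaling and without the 6 cells, to 4 under average linkage and to 2 with 10 components, and the cause was not tested. No cell met the rule for weak cells, so that setting changed nothing, and rescaled library sizes from counts were not run because the values are RPKM. No paired analysis was possible because there is 1 group. Because RPKM divides by length, 10 RPKM at the median depth is 126 reads of Lepr but 18.1 of Agrp.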

Other observations

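Clock genes differed from cell to cell. Cry2 was detected in 22 cells, Per1, Nr1d1 and Dbp in 16 each, Arntl, Cry1 and Nr1d2 in 13 each, and Clock in 2, with 3 to 9 of the 12 listed genes per cell. Genes of neurite growth and injury were mixed: Gap43 was in all 25 cells at a median of 427.5 RPKM, Sox11 in 11, Gadd45a in 10 and Atf3 in 6, while Sprr1a was in none. The synaptic release genes Syp, Vamp2 and Rab3a were in all 25 cells, and all 12 oxidative phosphorylation and 12 ribosomal protein genes were in every cell. Tbx19 was detected in 7 cells (10, 13, 14, 24, 25, 32 and 43) at a median of 106.5 RPKM, and Maob in 13.

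Single cells stood apart in ways no comparison covers. Cell 10 held 2 of the 16 immediate early genes, with Fos, Jun, Dusp1, Fosb and Nr4a1 at 0, while the next lowest, cell 4, held 6. Cell 29 carried Pomc, Cartpt, Prdm12, Nhlh2, Tbx3 and Isl1, all 6 Pomc markers, together with Agrp and Npy. Cell 17 had Htr3b at 238 RPKM and Crabp1 at 615 RPKM. Cell 5 had Lhx1 and Slc18a2 with Th at 0.

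The tests in the following paragraphs on depth, on Npy beside Agrp and on the ceiling were chosen after the values were seen; those on the nuclear list and on neighbouring genes were written before. Malat1 and Meg3 were low in the same cells: in cells 1, 3, 5, 6, 29 and 31 Malat1 was at most 16.6 RPKM and Meg3 at most 17.9 RPKM, and in the other 19 both exceeded 45 RPKM. Kcnq1ot1, another nuclear RNA, was at most 0.05 RPKM in those 6. Depth argues against a counting effect, since the median Malat1 level would give about 650 reads in the shallowest cell. The pattern could come from missing nuclear RNA, for example a nucleus lost in picking or lysis. The mean correlation of 6 other nuclear RNAs with the 3 (r = 0.275) exceeded that of 99.79% of random lists. This rests on Snhg11 (r = 0.917), and without it the list ranked at 89.4%. Miat (0.536) and Ftx (0.338) were positive too, but Rmst (0.110) and Peg13 (0.0489) were near 0 and Tug1 was negative (-0.303). The cause therefore stays open. No biological explanation was tested.

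Agrp at 10 RPKM or more without Npy was found in 7 of 9 cells. Free RNA from Agrp neurons should bring Npy too, and 22.2% of the Agrp cells listed it above 0 (interval 2.81 to 60.01%). This share cannot decide, because the cells are few and the 7 were set apart by Npy at 0. The other 2, cells 29 and 34, held Npy at 90.9 and 208 RPKM. Reads of neighbours could also be counted to Agrp, whose annotated span on chromosome 8 (105566698 to 105637393, GRCm38) overlaps the start of Ctcf on the other strand (105636568 to 105682922). The correlation of Agrp with Ctcf ranked at 88.6% of genes of like level and that with Atp6v0d1 at 12.5%, which leaves the question open. No biological explanation was tested.

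The highest values lay in a narrow band in every cell. A ceiling near 1 read per base, as removal of duplicate reads could give, predicts lower top RPKM in deeper cells, with a slope of -1 of log2 mean RPKM on log2 depth if strict. The slope was -0.57 for the 50 highest genes (-0.61 to -0.55 when each cell was left out), against -0.70 for the 10 highest, -0.18 for genes ranked 301 to 1000, 0.0035 for those ranked 1001 to 2000 and 0.30 for those ranked 3001 to 4000. Single genes reached up to 1.49 reads per base and 19 cells held at least 1 gene above 1, which argues against a strict ceiling at 1 as far as the estimated depths hold. A softer or higher limit stays open, including one from removal of duplicate reads. So does a lower share for top genes where more low genes are counted. No biological explanation was tested.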
